A study of Mus musculus with 17 samples.

How the data were processed

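Deposited miRNA and construct read counts were used as the authors gave them, 1 table per library with mapped reads, reads placed but not counted as mapped, and unplaced reads. Per the submitters' processing notes, reads were aligned with BWA and counted with SAMtools, with mm9 as the genome; versions are not given in the sources used here. Per the labels, RNA was isolated with Trizol and a Zymo kit and libraries were made with an Illumina TruSeq kit, and screen DNA was isolated with a Qiagen kit, its SA-miR region amplified by PCR and the product cleaned with Ampure beads. All reads were single reads of 51 cycles. The mapped column was analysed. In the small RNA libraries 23.6% to 55.2% of reads were placed but not counted as mapped, and 12.7% to 26.3% were unplaced.

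Computing used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Locations came from GENCODE mouse release 21 on GRCm38 and were not mixed with the mm9 coordinates of the authors. The groups, comparisons and a set of other settings were fixed before the data were examined. Chosen after seeing the data were the restriction to abundant miRNAs, the use of placed reads, epi as the only adult library, the treatment of similar libraries, the minimum of 1e+06 reads, the other call thresholds of the smaller pool, strands from placed reads, and library size scaling for the shared comparison.

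Small RNA counts were tested with edgeR quasi-likelihood models and TMM scaling, with the sorts of 1 tumour summed, at a Benjamini-Hochberg adjusted p below 0.05. Adult, embryonic and tumour libraries entered 1 fit and shared its estimate of the spread. The comparison of sorts used the tumour as a block, that of HF with epi the stage, and that of P0 with E17 the compartment. Without that block the count in each was also 0. TMM factors ran from 0.528 in E17epi to 2.90 in Bulge. Ratios of arms were tested with limma on log2 ratios (CPM with a pseudocount of 1) for hairpins of at least 10 CPM. The overlap between tumour and embryonic changes was compared with 20 simulations of unchanged groups that shared the adult libraries.

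Named miRNAs followed 1 rule. For each tested comparison they were the 12 higher and 12 lower miRNAs with the largest log2 change among those past the threshold with a mean of at least 100 CPM on at least 1 side, together with both arms of miR-21a and up to 4 of the most abundant members of each list. For the papilloma they were 10 in each direction with the same sign in both sorts and a log2 ratio of at least 1, and for the arm ratios miR-21 and 5 hairpins in each direction. There were 14 lists: miR-17-92 and its paralogues, the miR-200 family, skin epithelial, let-7, reported oncomiRs, reported tumour suppressors, Dlk1-Dio3, pluripotency, fibroblast and smooth muscle, blood and immune, endothelium, skeletal muscle, melanocyte and neural. They were assembled from general knowledge of these miRNAs and tested with camera, at a preset correlation of 0.01 and at an estimated correlation, where at least 3 members were measured.

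Screen counts were turned into shares of each library. Libraries of fewer than 1000 reads were left out, which removed 1. The design written beforehand counted 107 tumour and 15 skin libraries as 1 pool, but the construct names showed a pool of 88 and a pool of 86 constructs that share only 1 name, so the pools were analysed apart. Recurrence used exact binomial tests of calls against the mean share in skin, composition used permutation tests with 100000 resamples, and abundance used edgeR, with library size only between tumours and skin and TMM between skin and embryos. Strands were assigned from the arm with more reads in the small RNA libraries, which classed 14 constructs of the main pool as minor arms. These were miR-23a-3p, let-7g-5p, miR-221-3p, let-7d-5p, miR-148a-3p, miR-200a-3p, miR-25-3p, miR-378-3p, miR-486-5p, miR-92b-3p, miR-125b-1-3p, miR-151-5p, miR-423-5p and miR-21-3p. The class rests on mapped reads and need not be the arm usually taken as minor.

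The pipeline was tested on simulated data in which known changes were added to 50 miRNAs per fold. For tumour against adult, 10%, 54%, 86% and 100% of changes of 2, 4, 8 and 16 fold were recovered. For embryonic against adult the values were 26%, 90%, 96% and 100%, and for tumour against embryonic 4%, 74%, 98% and 100%. They were 0%, 46%, 74% and 90% between sorts, 4%, 50%, 86% and 96% between HF and epi, and 6%, 56%, 84% and 94% between P0 and E17. In the screen 89.5% of constructs enriched 20 fold were found by calls, and edgeR found 10% of 4-fold and 60% of 16-fold changes between tumours and skin, and 40% and 100% between skin and embryos.

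Alternatives covered scaling, the test, the filter, mapped with placed reads, single sorts, a different reference, other call thresholds and leaving out each library or cohort. Sequence reads, targets of the miRNAs and the effect of each construct on growth were not analysed here.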

Results

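Small RNA was sequenced from skin epithelial cells that had been sorted by their surface levels of integrin A6 and integrin B1, receptors that anchor basal progenitor cells to the basement membrane. A separate in vivo screen counted lentiviral constructs in the DNA of embryos, skin and skin tumours. The small RNA part held 12 libraries from female CD1 mice, with 3 adult populations titled Bulge, ORS and epi, 5 libraries labelled embryonic and titled E12All, E17epi, E17HF, P0epi and P0HF, and 4 tumour libraries. The tumour libraries were a high and a low integrin sort from each of 2 HRas-induced tumours: SCC47, labelled squamous cell carcinoma (SCC), and SCC63A, labelled benign papilloma although its title begins with SCC. Counts were given for 1908 mature miRNAs, the short RNAs that repress matching mRNAs. Mapped reads ranged from 730475 in the high sort of SCC63A to 13532663 in E12All, with a median of 4697878.

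The screen held barcoded libraries of C57BL/6 mice of both sexes, transduced in utero with a pooled lentiviral library of engineered miRNA constructs that the labels call SA-miR. Embryos were collected at E12.5, and tumours and adjacent skin came from animals that received the carcinogen DMBA and the tumour promoter TPA from postnatal day 50. Construct names divided the libraries into a main pool of 88 constructs (83 miRNA constructs and 5 scrambled controls) and another pool of 86 constructs. The main pool was counted in 3 embryo libraries, 14 skin libraries and 96 tumour libraries, and the other pool in 1 skin library and 11 tumour libraries. Reads per library ran from 828 to 42333834, with a median of 1018905. The tumour library of 828 reads was left out, which left 38 tumour libraries in cohort A, 37 in cohort B and 20 in cohort C. The labels do not say that libraries of one group came from separate animals, so the spread between these samples may be technical in part. Tests that compare groups of libraries measure that spread. The exact binomial tests of calls do not. They treat every call as an independent draw against a fixed mean skin share, so their p-values can be too small.

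To find miRNAs that distinguished tumour cells from normal adult progenitors, the 2 tumours, each the sum of its sorts, were set against the 3 adult populations. The fit also held the embryonic libraries, so the spread behind each p-value came from all classes together. Each adult library was a different sorted population, so the adult spread includes differences between populations. miR-21a-5p, a widely studied oncogenic miRNA, and miR-31-5p, a miRNA of growing and wounded epidermis, had the largest increases among the named miRNAs. miR-21a-5p stood at 42734 ± 43336 TMM-scaled CPM (counts per 1e+06 reads; SD, n = 2 tumours) against 336 ± 444 in adult skin (n = 3), a log2 change of 6.99 ± 1.37 (SE; edgeR adjusted p = 0.0157). In CPM of each library's own total, the tumour libraries held between 22581 and 154409 and the adult libraries between 185 and 518. The opposite arm of the same hairpin, miR-21a-3p (miR-21* in older naming), rose by 3.17 ± 0.73 on the log2 scale (edgeR adjusted p = 0.0317), to 448 ± 327 CPM from 49.7 ± 9.29. miR-31-5p rose by 6.03 ± 1.36 (edgeR adjusted p = 0.0291) and miR-128-2-5p by 4.29 ± 0.62 (edgeR adjusted p = 0.00588).

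**Figure D1:**
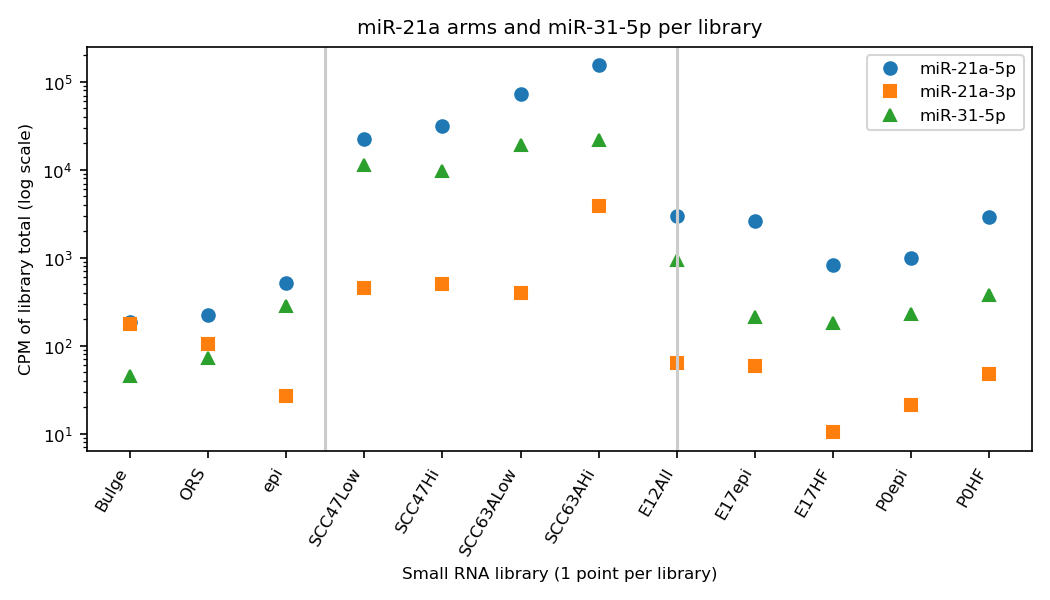
CPM of each library's own total (log axis) for miR-21a-5p, miR-21a-3p and miR-31-5p in 12 small RNA libraries, ordered as adult, tumour and embryonic; each point is 1 library. miR-21a-5p lies between 22581 and 154409 in the 4 tumour libraries and between 185 and 518 in the 3 adult libraries.

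Of 1865 miRNAs tested between tumour and adult cells, 80 changed, 64 higher and 16 lower, and 351 had an unadjusted p under 0.05. The other named miRNAs that rose were miR-125b-1-3p (log2 change 3.47), miR-7036-3p (3.40), miR-6902-5p (3.31), miR-126b-5p (3.21), miR-3471 (3.14), miR-448-5p (2.92), miR-6968-5p (2.86) and miR-7648-3p (2.72). Those that fell were led by miR-290a-3p, from a cluster active in embryonic stem cells, with a log2 change of -5.27 ± 1.17 (23.7 ± 6.85 CPM in tumours, 917 ± 911 in adult skin; edgeR adjusted p = 0.0276). miR-181c-5p fell by 4.34 (edgeR adjusted p = 0.0309), from 1934 CPM to 95.7. The rest that fell were miR-7054-5p (-2.84), miR-6943-3p (-2.80), miR-26a-2-3p (-2.56), miR-6915-5p (-2.50), miR-7054-3p (-2.39), miR-6960-5p (-2.25), miR-328-3p (-2.19), miR-7094-1-5p (-2.06) and miR-598-3p (-2.04). With placed reads added to the mapped ones, 9 of the 23 named changes stayed past the threshold and 12 were lost. The other 2 turned, miR-7036-3p to -0.83 and miR-7094-1-5p to 3.53. Several abundant skin miRNAs did not pass the test: miR-205-5p had a log2 change of -1.23 ± 1.15 (edgeR adjusted p = 0.575), miR-203-3p of -0.48 and miR-10b-5p of -0.39. In the GRCm38 annotation Mir21a lies on chromosome 11 (86584067 to 86584158, minus strand) in a UTR exon of Vmp1, Mir31 on chromosome 4 (88910557 to 88910662, minus strand) in a lincRNA exon, Mir128-2 on chromosome 9 (112118636 to 112118711, minus strand) in an intron of Arpp21, and Mir181c on chromosome 8 (84178873 to 84178961, minus strand) in an intron of Nanos3.

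Among the fixed miRNA lists, reported oncomiRs held 4 called members of 29 tested, all higher in tumours, and reported tumour suppressors 2 of 27, also higher. Lists held both arms of a hairpin and could share members. The called oncomiRs were both arms of miR-21a, miR-31-5p and miR-155-5p. The called tumour suppressors included miR-125b-1-3p, a minor arm that is also in the skin epithelial list. Its major arm miR-125b-5p had a log2 change of -0.26 and was not called. The oncomiR list was not past the threshold of camera, a test of a list against the other miRNAs (adjusted p = 0.071 with the preset correlation and 0.805 with an estimated correlation). Tumour suppressors leaned higher and the let-7 family, a set of differentiation miRNAs with 0 of 22 members called by edgeR and 4 at an unadjusted p under 0.05, leaned lower, each at adjusted p = 0.0384 with the preset correlation and 0.805 with an estimated correlation. The skin epithelial list had 2 of 22 members called, both higher (adjusted p = 0.304). The miR-200 family had 0 of 10 called by edgeR (0 at an unadjusted p under 0.05; adjusted p = 0.447), and the miR-17-92 list 0 of 28 (7 at an unadjusted p under 0.05; adjusted p = 0.51), with a median log2 change of 0.12 that was 0.03 with DESeq2 size factors and -0.02 with library size only. In the pluripotency list 2 of 24 members were called, miR-295-3p higher (log2 change 2.18) and miR-290a-3p lower (adjusted p = 0.516). The imprinted Dlk1-Dio3 cluster had 1 of 97 called and 0 when adjusted over the list alone (12 at an unadjusted p under 0.05; adjusted p = 0.619). Adjusting over the list alone left the other counts as they were, except in the blood list below.

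Lists of other cell types held few called members between tumour and adult libraries. The fibroblast list had 0 of 10 members called by edgeR (1 at an unadjusted p under 0.05; adjusted p = 0.447) and a median log2 change of 0.13, which was -0.04 with DESeq2 size factors and -0.19 with library size only. miR-143-3p, abundant in smooth muscle, had a log2 change of 3.36 ± 1.31 that did not pass (edgeR adjusted p = 0.184). The blood list had 0 of 13 called, or 2 higher when adjusted over the list alone (3 at an unadjusted p under 0.05; adjusted p = 0.447), and the endothelial list 0 of 2 (0 at an unadjusted p under 0.05). Neural miRNAs had 3 of 17 called, all higher, among them miR-128-2-5p and miR-9-5p (log2 change 1.77; adjusted p = 0.663), skeletal muscle 1 of 9, miR-133a-5p, lower (-1.59; adjusted p = 0.871), and melanocyte miRNAs 0 of 4 (1 at an unadjusted p under 0.05; adjusted p = 0.691).

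These tumour calls depended on single libraries. The total of 80 became 24 without Bulge, 12 without ORS, 232 without epi, 27 without SCC47 and 24 without SCC63A. With epi as the only adult library edgeR called 0 of 1870 (187 at an unadjusted p under 0.05; smallest adjusted p 0.0594; no other tool was run), with miR-21a-5p at 5.70 (adjusted p = 0.230) and miR-31-5p at 4.62 (adjusted p = 0.251). That lone library was assumed to vary like the other groups. A single library also gives little power, so the loss of calls alone does not decide about the changes. In size, both were smaller than in the main fit (6.99 for miR-21a-5p and 6.03 for miR-31-5p). Scaling by library size only gave 13 (11 higher, 2 lower), DESeq2 size factors 75 (52 higher, 23 lower) and the DESeq2 test about 2.0e+02, of which 98 were higher. The median log2 change over all miRNAs was -0.01 with TMM, -0.16 with DESeq2 size factors and -0.19 with library size only. miR-21a-5p narrowly missed the threshold without Bulge and gave 6.55 without ORS (edgeR adjusted p = 0.0639) and 5.11 without SCC63A (0.062), but 9.06 without epi (0.00577) and 7.77 without SCC47 (0.0236). miR-21a-3p gave 3.34 without Bulge (0.104), 3.10 without ORS (0.136) and 1.96 without SCC63A (0.285), and miR-31-5p 5.49 (0.0746), 5.54 (0.102) and 4.81 (0.0903). miR-290a-3p was not past the threshold without ORS (0.0603), SCC47 (0.212) or SCC63A (0.113), nor was miR-181c-5p (0.0639, 0.241 and 0.0692), whereas miR-128-2-5p passed whichever library was left out. Of the 23 named miRNAs that changed, 10 remained without Bulge, 2 without ORS, 22 without epi, 8 without SCC47, 5 without SCC63A, 23 without E12All, 17 without E17epi, 16 without E17HF, 18 without P0epi and 16 without P0HF. Scaling by library size only kept 7 of these 23, and a fit of only the classes compared kept 4. With the embryonic libraries of each stage summed 14 were kept.

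The embryonic and newborn libraries were compared with adult skin to find miRNAs of the growing epithelium. The 5 libraries, which include an epi and an HF library at both E17 and P0, were counted as independent. The sources used here do not name the animals behind them, so libraries of 1 stage may share animals. miR-298-5p had the largest change, at 16726 ± 7837 CPM (n = 5) against 22.6 ± 6.06 (n = 3), a log2 change of 9.53 ± 1.05 (edgeR adjusted p = 9.51e-06). Mir298 lies on chromosome 2 of GRCm38 (174267504 to 174267585, minus strand) and overlaps no other annotated gene. miR-296-5p and miR-296-3p rose with it (6.63 and 6.17), as did miR-322-3p (7.63), miR-455-5p (6.37), miR-196a-1-3p (6.24), miR-130b-3p (5.84 ± 0.74) and miR-335-5p (5.83). Members of the imprinted Dlk1-Dio3 cluster were also among the largest increases, namely miR-541-5p (6.92), miR-410-3p (6.45), miR-411-5p (6.05) and miR-434-3p (6.00). These 4, miR-196a-1-3p and miR-335-5p were far higher in E12All than in the other embryonic libraries (miR-541-5p 5582 CPM, next 358), and without E12All their changes were smaller but still past the threshold (4.45, 4.21, 4.46, 4.36, 4.17 and 2.85). miR-141-3p, a member of the epithelial miR-200 family, fell by 6.39 ± 0.73 (edgeR adjusted p = 1.3e-05), to 41.1 ± 31.3 CPM from 3440 ± 1753.

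The other named miRNAs lower in embryonic libraries were miR-451b (log2 change -7.78), miR-1193-3p (-7.39), miR-7233-5p (-6.62), miR-3066-3p (-6.55), miR-6896-5p (-6.39), miR-6370 (-6.35), miR-218-2-3p (-5.98), miR-670-5p (-5.88), miR-871-5p (-5.67), miR-181a-5p (-5.31) and miR-376c-5p (-5.24). Of 1865 miRNAs tested, 1009 changed, 492 higher and 517 lower (1118 at an unadjusted p under 0.05). miR-21a-5p was 3344 ± 1810 CPM in embryonic libraries, a log2 change of 3.32 ± 1.08 (edgeR adjusted p = 0.0192), and miR-21a-3p changed by 0.39 ± 0.58, within the spread (edgeR adjusted p = 0.595). The miR-21a-5p call was lost without Bulge (2.82; adjusted p = 0.0588) and without ORS (2.87; adjusted p = 0.0742). All 24 named changes remained whichever library was left out, and the count stayed between 799 and 1103. With the libraries of each stage summed all 24 also remained. With epi as the only adult library the count was about 4.1e+02 and 18 of the 24 remained; Bulge and ORS had TMM factors of 2.90 and 2.36, and epi of 0.611. Scaling by library size only shifted the median log2 change of all miRNAs to -1.48, from 0.08, and 981 of its 1114 calls were lower.

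The miR-17-92 list, miRNAs of a cluster that drives proliferation, moved most clearly as a group. Of 28 members, 18 rose and 4 fell (19 and 4 when adjusted over the list alone), with adjusted p = 0.00172 with the preset correlation and 0.161 with an estimated correlation. Examples were miR-20a-5p (log2 change 5.47), miR-17-5p (3.97) and miR-93-5p (2.75), while the most abundant member, miR-92a-3p, had a change of 1.17 that did not pass. With library size only 10 members rose and 8 fell, at a median of 0.23, which was 1.71 above the median of all miRNAs. Of the 22 members of the skin epithelial list, 9 rose and 1 fell (adjusted p = 0.0225, or 0.948 with an estimated correlation), and with library size only 6 rose and 3 fell at a median of -0.16, which was 1.32 above that of all miRNAs. miR-205-5p, the most abundant of the skin list, had a log2 change of 1.41 that did not pass (edgeR adjusted p = 0.218).

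Of the remaining lists most held members that rose and members that fell in embryonic libraries, and with library size only the median of each except the endothelial list was below 0. Of the Dlk1-Dio3 members 31 rose and 28 fell out of 97 (adjusted p = 0.997), of let-7 3 rose and 6 fell out of 22 (0.601), and of the pluripotency list 5 rose and 8 fell out of 24 (0.601), with miR-290a-3p (-3.69), miR-302b-3p (-4.07) and miR-291a-3p (-4.85) lower. In the miR-200 family 4 rose and 2 fell out of 10 (0.601), or 4 and 3 when adjusted over the list alone, with miR-200c-3p higher (2.22) and miR-141-3p lower. Reported oncomiRs had 9 higher and 4 lower of 29 (0.32; 8 and 4 when adjusted over the list alone) and tumour suppressors 10 and 3 of 27 (0.352; 9 and 3 when adjusted over the list alone). Fibroblast miRNAs had 4 higher of 10 (0.573), including miR-214-3p (3.42) and miR-143-3p (3.50), endothelial miRNAs 2 higher of 2, and blood miRNAs 5 higher and 3 lower of 13 (0.827), with miR-146a-5p lower (-3.40). Skeletal muscle had 3 higher and 1 lower of 9 (0.601), melanocyte 1 lower of 4 (0.997) and neural 5 higher and 6 lower of 17 (0.997). All values in brackets after list counts are camera adjusted p with the preset correlation.

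In the direct contrast of tumour with embryonic cells, miR-298-5p was again at the extreme, with a log2 change of -8.28 ± 1.20 (edgeR adjusted p = 0.000216; 53.9 ± 47.8 CPM, n = 2 tumours). miR-181c-5p fell by 6.91 (edgeR adjusted p = 0.000451), from 11504 CPM to 95.7, together with its other arm miR-181c-3p (-5.12). miR-29a-3p, often lost in tumours of other tissues, rose by 4.82 ± 0.82 (edgeR adjusted p = 0.000587), to 999 ± 831 CPM from 35.4 ± 31.5. Mir29a lies on chromosome 6 of GRCm38 (31062660 to 31062747, minus strand), outside other annotated genes. miR-21a-5p and miR-21a-3p both rose, by 3.68 ± 0.99 (edgeR adjusted p = 0.0103) and 2.78 ± 0.62 (edgeR adjusted p = 0.00313). Without SCC63A the changes were 1.78 (adjusted p = 0.242) and 1.67 (adjusted p = 0.0993).

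Of 1865 miRNAs, 781 differed between tumour and embryonic cells, 462 higher and 319 lower (935 at an unadjusted p under 0.05). The others named as higher were miR-1193-3p (log2 change 6.49), miR-451b (6.32), miR-6370 (5.66), miR-3066-3p (5.39), miR-141-3p (5.20), miR-7680-3p (5.14), miR-670-5p (5.06), miR-7118-3p (4.84), miR-6896-5p (4.78), miR-871-5p (4.77) and miR-218-2-3p (4.71). The others named as lower were miR-296-3p (-6.32), miR-130b-3p (-6.11), miR-455-3p (-5.27), miR-455-5p (-5.13), miR-301a-3p (-5.03), miR-322-3p (-4.89), miR-1932 (-4.88), miR-434-3p (-4.87) and miR-410-3p (-4.64). The total was 436 without SCC47 and 442 without SCC63A, and 20 and 22 of the 24 named changes remained. With library size only the median of all miRNAs was 1.46 in place of 0.07, and the 953 calls split into 874 higher and 79 lower. The DESeq2 size factors gave 391 higher and 353 lower, with a median of -0.05.

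The miR-17-92 list was lower in tumours than in embryonic cells, with 17 of 28 members lower and 2 higher (19 and 2 when adjusted over the list alone; adjusted p = 0.00015, or 0.0829 with an estimated correlation). With library size only 7 rose and 7 fell, and the median of -0.19 was -1.65 relative to all miRNAs. miR-17-5p fell by 3.82 and miR-20a-5p by 4.26, the latter with adjusted p = 0.0807 without SCC47. No other list passed: the smallest of the others was the skin epithelial list at 0.0904, with 2 higher and 4 lower (2 and 2 when adjusted over the list alone). The miR-200 family had 2 higher and 4 lower (0.637), let-7 5 and 4 (0.936; 6 and 5 when adjusted over the list alone), oncomiRs 6 and 5 (0.954), tumour suppressors 4 and 3 (0.96; 4 and 0 when adjusted over the list alone) and Dlk1-Dio3 19 and 13 (0.96; 16 and 9 when adjusted over the list alone). Pluripotency miRNAs had 8 higher and 4 lower (0.954), blood 3 and 2 (0.96), fibroblast 0 and 1 (0.936; 0 and 0 when adjusted over the list alone), endothelium 0 and 1, skeletal muscle 2 and 3 (0.936), melanocyte 1 and 0 (0.998) and neural 7 and 4 (0.998; 7 and 5 when adjusted over the list alone). With library size only the median of each of these lists except the endothelial one was above 0.

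Tumour and embryonic cells were then compared for miRNAs that moved in the same direction away from adult skin. There were 42 such miRNAs, 32 higher and 10 lower, and 2 that moved in opposite directions. Shared increases included miR-21a-5p, miR-125b-1-3p, miR-296-5p, miR-322-3p and miR-155-5p, an oncogenic miRNA of immune cells (log2 change in tumours 2.13). Shared decreases included miR-290a-3p. Of these, miR-155-5p was chosen after its values were seen. In tumours miR-21a-5p stood at 42734 TMM-scaled CPM, miR-125b-1-3p at 356 and miR-290a-3p at 23.7. The others were low, with miR-155-5p at 6.90 (1.45 in adult skin), miR-322-3p at 7.41 (1.15) and miR-296-5p at 19.6 (3.68). Most of the 42 lay below miR-290a-3p in tumours. Most also carry high miRNA numbers, and reads of such miRNAs are used below as a sign of background. Whether background reads add to the overlap was not tested. Independent lists of the same sizes as the tumour and embryonic lists would share 16.9 higher and 4.44 lower. The correlation of the log2 changes across miRNAs, which are not independent replicates, was 0.518. Unchanged groups simulated against the same controls gave 0.513 (0.475 to 0.568). Those groups held no changes, so this match cannot tell how far shared controls account for the observed correlation. The covariance was 0.986 against 0.139 simulated, which also grows with the size of the changes. The simulated unchanged groups shared 0 miRNAs against the 42 observed. Their expected overlap was also 0, so they cannot show how much shared controls add to lists of changed miRNAs. The 3 adult libraries are too few to give each side its own controls, so the overlap may come from the shared controls. The overlap was 14 without Bulge, 5 without ORS (miR-155-5p, miR-3074-5p, miR-5134-3p, miR-6936-3p and miR-7050-3p) and 172 without epi, and 4 with library size only (miR-143-3p, miR-21a-5p, miR-290a-3p and miR-31-5p).

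Between sorts, compartments or stages no miRNA passed the threshold with edgeR and TMM scaling. Between the high and low integrin sorts of the 2 tumours edgeR called 0 of 1867 miRNAs (63 at an unadjusted p under 0.05; smallest adjusted p 0.969), and DESeq2 called 1, miR-142b (log2 change 2.75; adjusted p = 0.0263). miR-21a-3p had a log2 change of 2.44 ± 1.18 toward the high sort, and neither arm of miR-21a was past the threshold. Scaling by library size only moved the median of all miRNAs from 0.02 to -0.76 and called 1, miR-141-3p (-5.07; edgeR adjusted p = 0.0226); these calls were named after their values were seen. The skin epithelial list leaned toward the high sort at adjusted p = 0.00451 with the preset correlation and 0.898 with an estimated correlation. Between HF and epi libraries of E17 and P0 edgeR called 0 (16 at an unadjusted p under 0.05) and DESeq2 0, with miR-21a-5p at 0.01 ± 1.65, and the blood list had adjusted p = 0.0138, or 0.611 with an estimated correlation. Between P0 and E17 edgeR called 0 (23 at an unadjusted p under 0.05) and DESeq2 0, with miR-21a-5p at 0.00 ± 1.71, a median of all miRNAs of -0.04 (0.17 with library size only) and a smallest list adjusted p of 0.179, for the Dlk1-Dio3 cluster (0.947 with an estimated correlation).

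The arms of the miR-21 hairpin were compared next, since the series title names miR-21* apart from miR-21. The 3p arm made up 48.6% of miR-21 arm reads in Bulge (exact 95% confidence interval 45.5 to 51.6), 31.7% in ORS (29.1 to 34.4) and 4.94% in epi (4.00 to 6.03). In tumour libraries it made up 1.98% and 1.57% in the low and high sort of SCC47 and 0.529% and 2.43% in those of SCC63A, and in embryonic libraries between 1.23% in E17HF and 2.19% in E17epi. Bulge and ORS were also the adult libraries with the most reads of miRNAs numbered 1000 or above (12.1% and 9.48%, against 2.57% in epi), so the arm share moved together with this sign of background reads. These shares rest on few reads in adult skin, with 546 reads of the 5p and 516 of the 3p arm in Bulge and 1751 and 91 in epi. Intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

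Of 318 hairpins with both arms measured, 18 changed their ratio of minor to major arm between tumour and adult cells, 10 toward the minor arm and 8 away from it (61 at an unadjusted p under 0.05). The miR-21a ratio changed by -4.48 ± 0.93 on the log2 scale (limma adjusted p = 0.0177) and that of miR-31 by -6.42 ± 0.97 (limma adjusted p = 0.00448), so in both hairpins the major arm gained more. The ratios of miR-6902 (-3.90), miR-7018 (-3.34) and miR-7068 (-3.05) also fell. Ratios that rose were those of miR-290a (4.34), miR-3620 (3.39), miR-543 (3.30), miR-6915 (3.16) and miR-181c (2.99). Without SCC63A limma called 0 of 319 hairpins, with miR-21a at -4.00 (adjusted p = 0.120) and miR-31 at -6.29 (adjusted p = 0.0563), and no other tool was run on these ratios. The miR-21a call was also lost without ORS (-4.13; adjusted p = 0.0795) and SCC47 (-4.95; 0.101), with changes about as large as before, and the total was 11 without Bulge, 6 without ORS, 72 without epi and 4 without SCC47 (miR-31, miR-6902, miR-6977 and miR-7056, named after their values were seen).

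The tumour labelled papilloma and the one labelled SCC were set side by side sort by sort, without a test because there was 1 tumour of each kind. Of 436 miRNAs with at least 100 CPM, 371 had a ratio of the same sign in both sorts, 19 were higher in the papilloma by at least 1 on the log2 scale in both sorts and 179 were lower. miR-181b-5p had log2 ratios of 3.82 in the high and 4.01 in the low sort, miR-27a-5p 3.93 and 3.14, and miR-125b-1-3p 3.61 and 2.61. miR-21a-5p was also higher in the papilloma (2.29 and 1.71), with miR-6966-3p (5.62 and 2.40), miR-142-5p (4.75 and 2.04), miR-615-3p (2.64 and 2.03), miR-224-5p (2.08 and 2.02), miR-340-5p (3.04 and 1.86) and miR-1a-2-5p (2.39 and 1.84). The lower ones were led by miR-7094-3p (-5.66 and -4.65), miR-7118-3p (-5.76 and -4.54), miR-7648-3p (-4.53 and -4.31), miR-1231-3p (-4.99 and -4.24) and miR-7024-5p (-4.34 and -4.01), followed by miR-7036-3p, miR-6909-3p, miR-6907-3p, miR-6970-3p and miR-207. The median ratio over all these miRNAs was -1.29 in the high and -0.91 in the low sort, and 4.36% were higher and 41.1% lower. With TMM-scaled values the balance turned, to 81 higher and 15 lower of 305 (26.6% and 4.92%).

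Of the lists, 2 of 15 measured skin epithelial miRNAs were higher in the papilloma and 0 lower, and 0 of 11 miR-17-92 members were higher and 3 lower. OncomiRs had 3 higher and 3 lower of 16, tumour suppressors 2 and 2 of 13, let-7 0 and 1 of 8, the miR-200 family 0 and 1 of 3, and Dlk1-Dio3 0 and 6 of 18. Pluripotency had 0 and 2 of 3, blood 1 and 2 of 6, neural 0 and 2 of 6, skeletal muscle 1 and 0 of 1, and fibroblast (3 measured) and endothelium (1 measured) none in either direction. These counts follow the scaling: with TMM-scaled values 11 of 15 skin epithelial miRNAs were higher, 4 of 11 miR-17-92 members were higher and 1 lower, oncomiRs had 8 higher of 14, tumour suppressors 9 of 13 and let-7 1 of 7, with 0 lower in each of these 3. With those values Dlk1-Dio3 had 2 higher and 1 lower of 10, blood 2 higher of 5, neural 1 of 3, pluripotency 1 of 3, fibroblast 1 of 3, skeletal muscle 1 of 1, and the miR-200 family and endothelium 0.

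The screen was examined first for how many constructs made up each library. The effective number of constructs (inverse Simpson index) had a median of 4.01 in 95 tumour libraries, 37.8 in 14 skin libraries and 41.4 in 3 embryo libraries. It was at least 10 in 32 tumour libraries, and the highest tumour value, 43.1, was above that of skin (41.5). The construct with the largest share took a median of 44.9% of tumour reads, 7.10% of skin reads and 5.15% of embryo reads, and it exceeded 50% in 39 tumour libraries and 90% in 11. The geometric mean of 5.48 in tumours was below that of skin by a log2 difference of -2.68 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 3e-05 over 3 comparisons). Against embryos the difference was -3.03 (exact permutation p = 0.000151; adjusted p = 0.000227), and between skin and embryos -0.35 (exact permutation p = 0.0838). Each cohort was below skin, by -2.62 in cohort A, -2.29 in cohort B and -3.50 in cohort C.

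**Figure D2:**
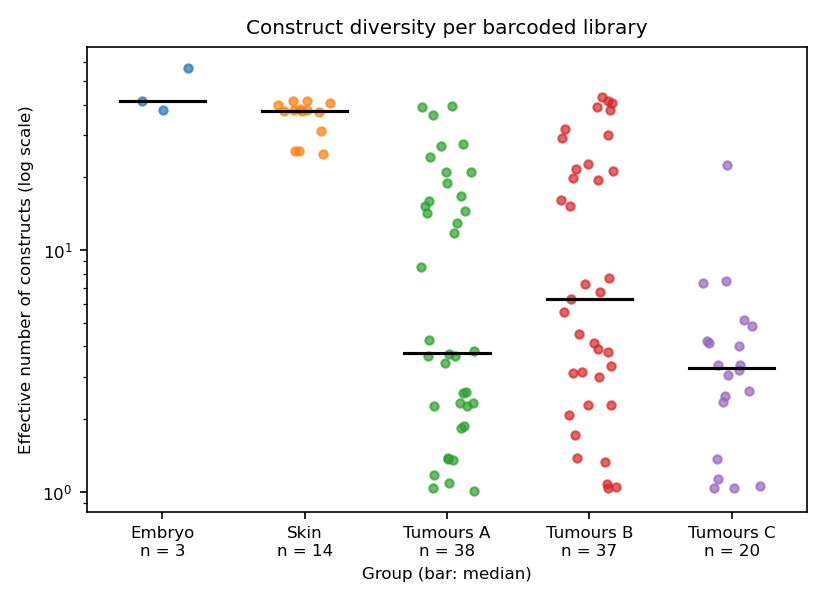
Effective number of constructs (inverse Simpson index of read shares, log axis) in embryo, skin and tumour libraries of the main pool, with tumours by cohort; each point is 1 barcoded library. Medians are 41.4 in embryos and 37.8 in skin, against 3.77 in cohort A, 6.27 in cohort B and 3.27 in cohort C.

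To ask which constructs recurred in tumours, a construct was called in a tumour library when it held at least 10% of the reads. The miR-21-3p construct, which carries miR-21*, was called in 45 of 95 libraries (47.4%), where its skin share gave an expectation of 1.30 calls, a 34.5-fold excess (exact binomial adjusted p = 2.06e-53). It was called in 10 of 38 libraries of cohort A, 16 of 37 of cohort B and 19 of 20 of cohort C (exact binomial adjusted p = 2.28e-08, 3.82e-18 and 2.75e-31). It made up 31.3% of all calls (exact 95% confidence interval 23.8 to 39.5), was the largest construct in 38 libraries and exceeded 50% in 22. Its mean share was 0.905% in skin (n = 14 libraries) and 1.08% in embryos. miR-21-3p was the only one of 88 constructs past the threshold, with 5 at an unadjusted p under 0.05, and 47 had at least 1 call.

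miR-29a-3p had 18 calls against 8.41 expected, miR-31-5p 9 against 2.79 and miR-125b-5p 7 against 1.79, each with exact binomial adjusted p = 0.0501. In single cohorts miR-29a-3p was past the threshold in cohort A with 13 calls (exact binomial adjusted p = 0.00225) and miR-31-5p in cohort B with 9 calls (4.86e-05). Without cohort C the constructs past the threshold were miR-21-3p, miR-29a-3p and miR-31-5p, and without cohort A miR-21-3p and miR-31-5p. miR-21-5p, the guide strand, had 7 calls against 4.20 expected (exact binomial adjusted p = 1), miR-429-3p 5 against 1.75 (0.568), and miR-181a-5p, let-7e-5p, miR-328-3p and miR-30b-5p 3 each. The 5 scrambled controls had 2 calls against 4.65 expected (two-sided exact binomial p = 0.338). In the other pool 13 calls fell on 10 constructs and the exact binomial test passed 0 of 86 (3 at an unadjusted p under 0.05; smallest adjusted p 0.798; no other tool was run), where miR-615-3p had 2 calls against 0.148 expected.

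**Figure D3:**
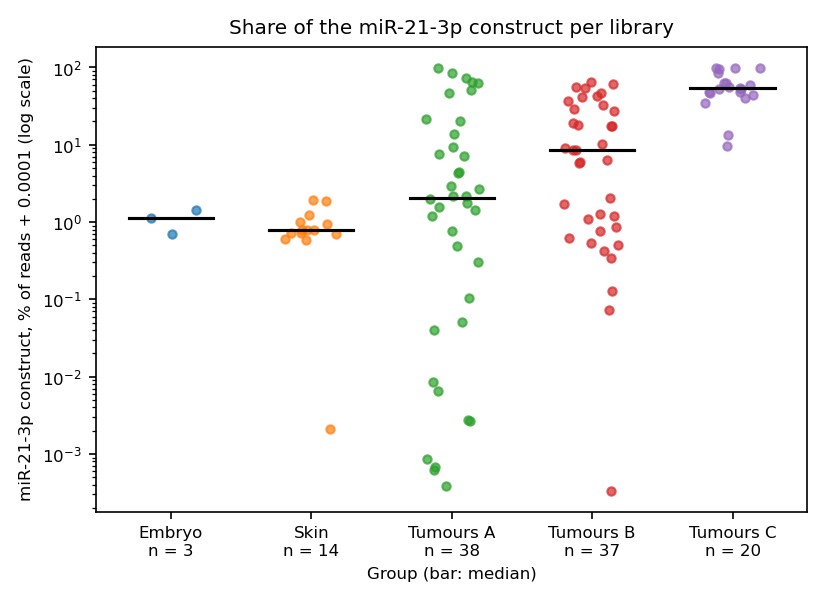
Percent of reads that belonged to the miR-21-3p construct in each barcoded library of the main pool (log axis, with 0.0001 added), in embryos, skin and tumours by cohort; each point is 1 library and the bar is the median. Over all tumour libraries the median is 9.04%, and 19 of 20 libraries of cohort C reach 10%.

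**Figure D4:**
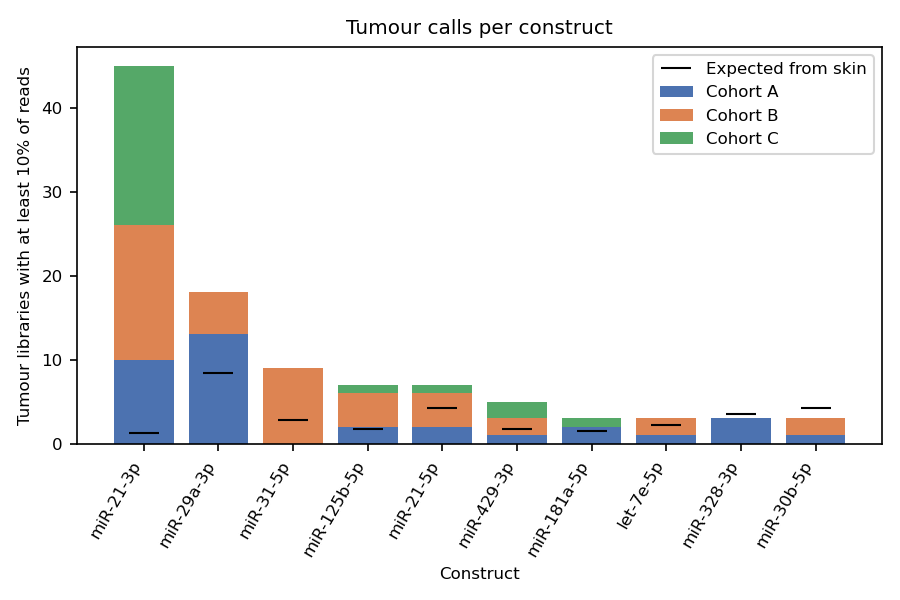
Number of tumour libraries in which each named construct held at least 10% of the reads, as bars divided by cohort, beside the number expected from its mean share in skin. miR-21-3p reaches 45 calls against 1.30 expected, and miR-21-5p 7 against 4.20.

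Both strands of miR-21 were in the pool and could be compared directly. Of the 52 calls of either strand, 45 were of miR-21-3p (86.5%, exact 95% confidence interval 74.2 to 94.4), where the skin shares gave 23.7% (two-sided exact binomial p = 1.54e-21). The proportion was 83.3% in cohort A, 80% in cohort B and 95% in cohort C. miR-21-3p had the larger share of the pair in 84 of 95 libraries, with a median share of 9.04% against 1.16% for miR-21-5p. Among all constructs, those classed as minor arms by mapped small RNA reads made up 54 calls (37.5%, exact 95% confidence interval 29.6 to 45.9; 14.8% by skin share; two-sided exact binomial p = 2.12e-11). This class need not be the arm usually taken as minor. With strands assigned from mapped and placed reads the values were 43.8% against 23.7% (two-sided exact binomial p = 1.19e-07). Without miR-21-3p they made up 9 of 99 (9.09%, against 14.1%; two-sided exact binomial p = 0.192). By cohort the proportion with miR-21-3p was 13 of 62 in A (p = 0.208), 38.2% in B (p = 1.92e-05) and 74.1% in C (p = 8.16e-12, exact binomial tests).

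Read counts were compared next. With edgeR and library size scaling, 3 of 88 constructs differed between tumours and skin (8 at an unadjusted p under 0.05). miR-21-3p rose by 4.79 ± 1.11 on the log2 scale (edgeR adjusted p = 0.00117), to 25.1% ± 29.6 of reads in tumours (SD, n = 95). miR-203-3p, a differentiation miRNA of the epidermis, fell by 4.27 ± 0.89 (edgeR adjusted p = 0.000367), and miR-10b-5p (-1), a construct whose start is shifted, fell by 3.06 ± 0.93 (edgeR adjusted p = 0.0370). The other constructs of these miRNAs, miR-203-3p (-1) and the unshifted miR-10b-5p, did not pass. In mean log2 shares miR-203-3p and miR-10b-5p (-1) changed by -7.25 and -8.07, and the 5 scrambled controls by -5.57 to -7.98. The call of miR-10b-5p (-1) was lost without cohort A (-2.69; adjusted p = 0.164) and without cohort B (-2.99; adjusted p = 0.0642), and without cohort A miR-22-3p passed instead (-3.86; adjusted p = 0.0391). With skin libraries of similar composition summed only miR-203-3p passed (-4.91), while miR-21-3p kept its size but missed the threshold (4.91; edgeR adjusted p = 0.0609). TMM passed only miR-21-3p (8.56). The embryo libraries as reference passed 0 by edgeR, while DESeq2 size factors in edgeR passed 71, all higher, and a permutation of log2 shares 86, of which 85 were lower. The DESeq2 test gave an adjusted p to 5 of the 88 constructs, which left out miR-203-3p and miR-10b-5p (-1), and 3 passed, all higher: miR-21-3p (13.4), miR-31-5p (9.15) and miR-127-3p (5.17). The median log2 change of all constructs was -0.66 with library size, -0.10 with TMM, 5.38 with DESeq2 size factors and -5.99 in log2 shares. miR-22-3p and miR-127-3p were named after their values were seen. Between skin and embryos edgeR called 0 of 88 constructs (3 at an unadjusted p under 0.05) and DESeq2 0.

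Cohorts resembled one another weakly in which constructs were called. Across the 88 constructs, which are not independent replicates, Spearman's rho of calls was 0.141 between cohorts A and B (permutation p = 0.188, adjusted p = 0.188), 0.242 between A and C (permutation p = 0.0167, adjusted p = 0.0251) and 0.276 between B and C (permutation p = 0.00986, adjusted p = 0.0251). Without miR-21-3p the values were 0.0916, 0.181 and 0.203.

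Finally, the small RNA changes were set beside the screen for 77 miRNAs measured in both. Across these miRNAs, which are not independent replicates, the log2 change between tumour and adult cells and the log2 excess of calls had Spearman's rho of 0.103 (permutation p = 0.370, adjusted p = 0.370) and Pearson's r of 0.173 (permutation p = 0.131, adjusted p = 0.227). Without miR-21 and miR-31 r was -0.133. With the tumour against embryonic change r was 0.311 (permutation p = 0.00744, adjusted p = 0.0298) and rho 0.158 (permutation p = 0.170, adjusted p = 0.227), and r was 0.152 without miR-21 and miR-31, so the relation rested on those miRNAs.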

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

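All tests named in this part were chosen after seeing the result, apart from the rule for values that stand apart from their group.

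In the 5 embryonic libraries 54 named values were tested for standing apart, which by chance happens in about 1 in 20 groups. E12All held miR-541-5p at 5582 CPM (next highest 358), miR-335-5p at 5424 (317), miR-196a-1-3p at 2737 (215), miR-411-5p at 2609, miR-410-3p at 2242 (169.8) and miR-434-3p at 1899 (332). miR-290a-3p was 194 CPM in E17HF, with 68.0 in the nearest library. miR-29a-3p was 92.9 CPM in P0HF, with 30.5 in the nearest library.

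Calls differed between cohorts for 3 of 10 constructs tested. miR-21-3p had 10, 16 and 19 calls in cohorts A, B and C (permutation adjusted p = 0.0001; raw p = 1e-05, the smallest possible), miR-29a-3p 13, 5 and 0 (permutation adjusted p = 0.0128) and miR-31-5p 0, 9 and 0 (permutation adjusted p = 0.00165).

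Of the reads of miR-23a-3p, 97.4% were placed but not counted as mapped (165 mapped and 6128 placed), against 45.2% for all miRNAs, so mapped counts leave most of its reads out.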

How the results depend on the processing

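Counts and main values were the same in 177 alternatives, moved in 44, stronger in 5 and weaker in 4, and a value past the threshold in neither setting was counted as same. The cause of each difference was not tested.

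For scaling, library size only gave 13 changed miRNAs in tumour against adult, 4 shared with embryonic cells and 1 between integrin sorts. It reversed miR-211-5p in embryonic against adult (-1.27) and miR-10b-5p in tumour against embryonic (1.41). The DESeq2 test gave about 2.0e+02 in tumour against adult and 1 between sorts.

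For the samples used, tumour against adult gave about 1.5e+02 with 4 libraries singly, 23 with only the classes compared, 30 without newborn libraries and 0 with epi as the only adult library (assumed to vary like the other groups), where embryonic against adult gave about 4.1e+02 and the overlap 0. Tumour against embryonic gave 422 with high sorts only. Abundant miRNAs alone gave 13 in tumour against adult, 208 in embryonic against adult, 179 in tumour against embryonic and 9 shared. With mapped and placed reads miR-7036-3p (-0.83) and miR-7094-1-5p (3.53) reversed in tumour against adult.

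Leaving out 1 library gave 12 (ORS) to 232 (epi) in tumour against adult, 799 to 1103 in embryonic against adult, 436 to 872 in tumour against embryonic, 5 to 172 shared and 0 to 72 arm ratios. miR-24-3p reversed without epi (-0.61 without Bulge to 2.16, embryonic against adult) and miR-1a-2-5p without SCC63A (-0.14, to 2.95 without SCC47, tumour against embryonic).

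Arm ratios gave 3 at 100 CPM, 39 without a filter and 32 with tumour libraries singly. The papilloma comparison gave 769 at 10 CPM and 96 with TMM-scaled CPM.

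Constructs past the threshold for calls numbered 4 at a call of 5%, 2 with the largest construct only, 4 with embryo shares, 3 with the larger of skin and embryo shares, 2 without cohort A, 3 without cohort C, 4 with near-identical libraries once, 2 with mapped and placed reads and 2 with at least 1e+06 reads. At a call of 5% cohorts A and B had rho 0.287 and the screen had Pearson's r of 0.280 with small RNA changes. At the call of 10% r was 0.311 with tumour against embryonic changes.

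Abundance in tumours against skin gave 1 with similar skin summed, 1 with TMM, 71 with poscounts, 86 by permutation and 0 against embryos. Poscounts in edgeR reversed miR-203-3p (2.12), miR-10b-5p (-1) (4.34), miR-29a-3p (4.75), miR-21-5p (7.76), let-7e-5p (5.76), miR-328-3p (7.58) and miR-30b-5p (7.61). The DESeq2 test reversed miR-203-3p (2.12) and miR-10b-5p (-1) (4.34), and permutation miR-429-3p (-4.55) and miR-181a-5p (-8.01).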

Other observations

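The lists in this paragraph and the tests of carry-over, read depth, scaling, consecutive barcodes and regrouped small RNA libraries were chosen after seeing the result, while the tests of background reads and of regrouped screen libraries were written before. Within the embryonic group, E12All, from the earliest stage, differed from the E17 and P0 libraries in many members of some miRNA families; these are values of 1 library. Most measured members of the imprinted Dlk1-Dio3 cluster were higher there: 49 members had a median log2 ratio of 2.64 to the other 4 libraries, 36 were above all 4 and 5 below all 4. Of the let-7 family, which accumulates as cells differentiate, 12 of 22 members were measured, with a median of -2.42 and 11 below all 4, and let-7e-3p lay within the range of the others. Fibroblast miRNAs were higher, with a median of 2.73 over 5 members and 4 above all 4.

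Reported oncomiRs had a median of 0.33 over 22 members in E12All, with 9 above and 6 below all 4 others, and skin epithelial miRNAs -0.57 over 18 members, with 4 above and 8 below. The medians of the other lists were -0.29 for miR-17-92, -0.44 for the miR-200 family, -0.05 for tumour suppressors, -0.29 for pluripotency, 0.22 for blood and 0.21 for neural miRNAs. The median of all 718 measured miRNAs was -0.17.

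The miR-21-3p construct was called in 45 of 95 tumour libraries. Hypothesis: it gave cells an advantage in tumours; alternatives are carry-over of 1 template, or chance dominance in libraries of few reads. Carry-over that gave at least 1% in every library of cohorts A and B was not seen, since 32% of these libraries held under 1% (bound 20%). The test cannot exclude carry-over of a smaller share into every library. In cohort C 0% held under 1%, which left carry-over open there. Carry-over into part of a cohort also stays open, because in cohort A barcodes 1 to 11 held at most 0.104% and barcodes 12 to 38 held 0.306% to 97.9%. In 43 libraries with more reads it had 15 calls, a 35.3-fold excess, so few reads did not account for all of the excess. That fold pools the cohorts, and the miR-21-3p share fell with read depth within cohorts A and B. Spearman's rho was -0.516 in A and -0.643 in B, against -0.0602 in C. A contribution of few reads therefore stays open within cohorts A and B. Whether carry-over underlies the fall with depth was not tested.

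More miRNAs were higher than lower in tumour against embryonic libraries (462 against 319), and of these 462, 380 were also called higher in adult than in embryonic libraries, 5 lower and 77 neither, an overlap expected at least in part because both comparisons share the embryonic libraries. Hypothesis: the difference belongs to development; alternatives are the scaling between libraries and background reads in some libraries. The share of higher calls was 59.2% with TMM, 52.6% with DESeq2 size factors and 91.7% with library size only, so scaling set the size of the imbalance and stays open. The test of background reads gave 0.99 against a bound of 1 set beforehand, which did not decide, but the median ratio of Bulge and ORS over epi was 2.58 for these miRNAs against 1.70 to 2.11 in random lists of matched abundance. Reads of miRNAs numbered 1000 or above made up 12.1% and 9.48% in Bulge and ORS, 10.6% and 6.70% in SCC47, 4.81% and 3.63% in SCC63A and 2.57% in epi, against 2.18% to 2.90% in embryonic libraries, so background reads could contribute.

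Skin libraries of the barcode pairs 1-2, 3-4, 5-6, 7-8 and 9-10 resembled each other, with a mean distance of 0.0809 against a median of 0.374 for random pairings (permutation p = 1e-05, the smallest possible), while the consecutive pairs between them (2-3, 4-5, 6-7 and 8-9) lay 0.391 to 0.453 apart and 13-14 lay 0.611 apart. Hypothesis: the close pairs are repeat libraries of 1 tissue; separate samples of 1 animal and a shared virus or library preparation are alternatives. An embryo library lay as close to skin libraries 9, 10 and 11 (0.0490 to 0.0550). Others lay 0.145 from skin 8 and 0.173 from skin 3, farther than any close pair (at most 0.121). The median over all pairs was 0.401. Going by the labels, such closeness arose without a shared tissue or animal for that 1 embryo library. Whether those labels hold was not tested, and the cause stays open.

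Libraries were also regrouped. Embryonic against adult reached its count of 1009 in 1 of 56 groupings, the real one, with 0 as the highest other. No share below 1 of 56 was possible, and mixed groupings put the difference of the classes into the spread, so few calls were likely in them. The count was tied to the real grouping, but this does not exclude chance. For skin against embryo the real count was 0, which all 100 groupings reach by definition, so this says nothing about chance; the highest was 19, which points to a structure of the samples that was not traced to particular libraries. For tumour against skin abundance 16 of 100 reached the real count of 3, with 7 as the highest, so chance cannot be excluded.

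In skin library 13 the miR-21-3p construct held 0.00198% of reads, while the other 13 held 0.584% to 1.91%. The miR-21-3p share fell with read depth within cohort B (Spearman's rho -0.643, permutation p = 4e-05, adjusted p = 0.00024; Pearson's r -0.578, permutation p = 0.00017, adjusted p = 0.00051; r -0.594 without the 2 libraries farthest in depth) and within cohort A (rho -0.516, permutation p = 0.00101, adjusted p = 0.00202; r -0.430, permutation p = 0.00594, adjusted p = 0.00891; r -0.314 without the 2 farthest). In cohort C rho was -0.0602 (permutation p = 0.801, adjusted p = 0.801) and r 0.549 (permutation p = 0.0318, adjusted p = 0.0382), which turned to -0.317 without the 2 farthest, so that r rested on those libraries.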
